A study of Homo sapiens with 9 samples.

How the data were processed

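Jurkat cells, a human T-lymphocyte leukaemia line, were grown in complete RPMI medium, and RNA was extracted from exponentially growing cells and made into libraries with a poly(A) selection kit, per the labels' protocols. The 9 libraries comprise 3 of the unedited line (WT) and 3 of each edited line (KO1 and KO2), and groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of FPKM values (fragments scaled by transcript length and library size) with a column per library and gene symbols as names. STAR 2.5.0b, Cufflinks 2.2.1, bedtools 2.7.0 and the genome build hg19 are named in the submitters' processing notes, without their order or role. The gene annotation, the strandedness of the counting and any scaling between libraries are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies, such as those of the MAGEA family and the ribosomal proteins, may share reads, so their values are uncertain.

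Of the 26228 rows of the table, 38, mostly genes of the MHC region, hold text in place of values and were left out, which removed EHMT2, TAP1, TAP2, PSMB8, HLA-DPA1 and POU5F1 from the gene lists. The T-cell receptor chain genes TRAC, TRBC1, TRBC2, TRGC1, TRGC2 and TRDC, the immunoglobulin gene IGHM and the listed names HEB, CD13 and ANPN were not matched to the table. Names that a spreadsheet had turned into dates (28 rows, 18 of them tested) were kept in the test and are not named. Values are normalized, so total counts per library are unknown and no counting interval is given. Sums of FPKM ran from 417737 to 439704 per library. Steps between low values gave relative depths of 0.96 to 1.16 against WT replicate 3, with the highest in WT replicate 1, so depth differed little between groups. An FPKM of 0 can be a failed estimate: 60 rows are at 0 in a library and at 20 or more in another, and 58 of them are small RNA genes. In KO2 replicate 1 the highest value belonged to the small nucleolar RNA SNORD49B, at 10219 FPKM. Pearson correlations of log2(FPKM + 1) across tested genes ran from 0.989 to 0.994 within groups, 0.931 to 0.94 between KO1 and WT, 0.946 to 0.953 between KO2 and WT, and 0.975 to 0.982 between the edited lines. There were 0 pairs of libraries with identical columns.

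FPKM are not counts, so no count model was used. Genes with FPKM of at least 1 in 3 or more of the 9 libraries were kept (11737 genes), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 9 libraries in the same fit, empirical Bayes moderation with a mean-variance trend and no covariates. Contrasts were KO1 against WT, KO2 against WT, KO2 against KO1 and the mean of the edited lines against WT. Benjamini-Hochberg adjusted p under 0.05 was the threshold, with no minimum fold. Standard errors are those of the moderated fit. For 35 gene lists fixed before the data were examined, limma's camera was run with a preset correlation of 0.01 on the 31 lists with at least 5 tested genes, and p-values were adjusted over lists. No list call in any of the 3 pairwise comparisons held with an estimated correlation. Listed symbols were matched directly or through older symbols and RefSeq synonyms; the exact rule for synonyms was settled after list results had been seen, and matching by exact symbol is given as an alternative. Named genes were chosen by a rule fixed beforehand: EZH2; the 12 largest rises and falls in both lines, by the smaller log2 fold change, among genes passing in both with no overlap between WT and edited libraries; the 6 largest differences in each direction between KO2 and KO1; up to 4 genes per list with the smallest p for the mean of the edited lines; and 15 genes of prior interest.

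The fit was tested on simulated data drawn from the real genes' means and spread, with 200 changed genes among 11737. The changed genes were taken only from those above a minimum mean level, so recovery of weakly expressed genes was not measured. In the data a far larger share passed, 67.5% of genes in KO1, 64.7% in KO2 and 30.6% between the edited lines. Adjusted p-values depend on that share, so the simulated recovery and false calls do not measure those of the real fits. For KO1 against WT, 96% of genes changed by 0.5 on the log2 scale and 28% of those changed by 0.25 were recovered, with 3 false calls. For KO2 against KO1 these shares were 94% and 38%, with 7 false calls. Shared controls were examined with 100 simulations of unchanged groups. Neighbouring genes were ordered by RefSeq positions on GRCh38.p14, used only for gene order: 93.2% of genes with a mean of 5 FPKM or more were placed, and running medians over 31 genes were compared with 100 shuffled orders; a planted run of 60 genes among 2000 was found in full. Alternatives tried were no filter and a filter at 5 FPKM, pseudocounts of 0.1 and 0.5, quantile normalization, median centring, robust moderation, no trend, fits of only the groups compared, stricter thresholds, a replicate block, fry, an estimated correlation and leaving out each library.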

Results

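The series measured polyadenylated RNA in Jurkat cells, an established human T-cell acute lymphoblastic leukaemia line, in 9 libraries. The unedited line, labelled WT, and the CRISPR/Cas9-edited lines labelled EZH2-KO1 and EZH2-KO2 contributed 3 libraries each, which the submitters describe as biological triplicates. EZH2 is the methyltransferase of Polycomb repressive complex 2, which places the repressive mark H3K27me3. The series title places the lines in a study of sensitivity to inhibition of CHK1, a checkpoint kinase activated during replication stress. The comparisons ask how the transcriptome of each edited line differed from that of the unedited line, and how the edited lines differed from each other. Values are FPKM, given as mean ± SD over 3 libraries. Log2 fold changes, given ± SE, are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. The libraries had 11028 to 11415 genes at 1 FPKM or more, their depth in reads is unknown, and 11737 genes were tested. Each edited line is a single line, so the p-values measure the spread between cultures and not the spread between independent edits.

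The EZH2 transcript was present in all 9 libraries and was higher in both edited lines. It stood at 77.2 ± 2.54 FPKM in WT and at 106 ± 2.5 in the libraries labelled KO1 (log2 fold change 0.45 ± 0.04, limma adjusted p = 1.64e-06). In those labelled KO2 it stood at 89.5 ± 1.4 (0.21 ± 0.04, adjusted p = 0.000541). A value over the whole transcript cannot show an edit that leaves the transcript in place, so it does not check the labels, and every direction below rests on the labels. EZH1, the paralogue of EZH2, was lower in both lines, at 11.8 ± 1.01 FPKM in WT, 7.15 ± 0.145 in KO1 and 7.72 ± 0.401 in KO2. The accessory subunits PHF19 and PHF1 also fell in both lines, whereas C17orf96 (EPOP) rose. Transcripts of the core subunits SUZ12 and EED had log2 fold changes between 0.05 and 0.10 that did not pass in either line (adjusted p = 0.092 to 0.604). SUZ12 passed in KO1 when WT replicate 1 was left out (0.16, adjusted p = 0.0382). Of the 13 tested genes of the complex, 3 rose and 7 fell in KO1, and 2 rose and 7 fell in KO2, with the same counts adjusted over the list alone. The list did not pass the set test in either line (camera adjusted p = 0.333 and 0.0915), although it passed in KO2 with lists matched by exact symbol (adjusted p = 0.0456).

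**Figure D1:**
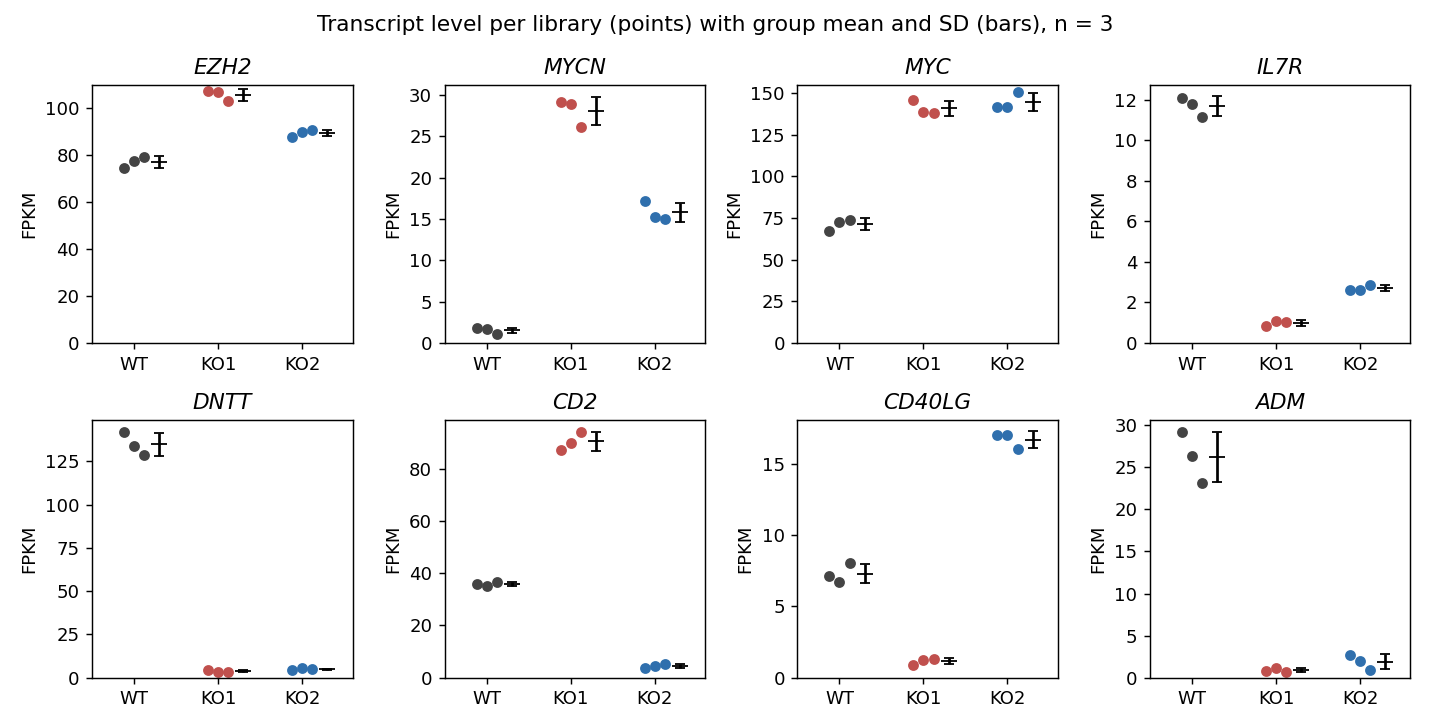
Transcript level (FPKM, vertical axis, starting at 0) of 8 genes in each library of WT, KO1 and KO2 (horizontal axis), where points are libraries and bars give the mean and SD of the 3 libraries. EZH2 was 77.2 in WT and 106 and 89.5 in the KO lines, MYCN went from 1.5 to 28.1 and 15.8, and CD2 and CD40LG moved in opposite directions in KO1 and KO2.

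In the comparison of the libraries labelled KO1 with WT, genes of glycolysis and the hypoxia response were lower, MYCN, MYC and MYC-activated genes were higher, and T-lineage transcripts were mostly lower. MYCN, a MYC family oncogene, rose from 1.5 ± 0.328 to 28.1 ± 1.7 FPKM, and MYC rose from 71.1 ± 3.65 to 141 ± 4.32. The list of the MYC family and its network did not move as a group: of 12 tested genes, 4 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.929). Its median was -0.12, its mean was 0.20 and its set test pointed down. All 30 tested genes of the glycolysis and hypoxia list fell (also 30 adjusted over the list alone), with a median log2 fold change of -1.30. The glycolytic enzyme PGK1 went from 906 ± 40.9 to 285 ± 2.24 FPKM, ENO2 from 125 ± 4.59 to 36.1 ± 2.25 and the hypoxia-induced NDRG1 from 36.2 ± 1.61 to 6.86 ± 0.267. The list passed the set test (camera adjusted p = 3.82e-16), a call that was lost with an estimated correlation (adjusted p = 0.207).

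Over all tested genes, 7923 changed in KO1, of which 4177 rose and 3746 fell (52.7% higher, and 49.5% after quantile normalization). A change of 2-fold or more was seen for 652 of the genes that rose and 334 of those that fell. Of 50 MYC-activated genes, 42 rose and 3 fell (43 and 3 adjusted over the list alone; camera adjusted p = 2.72e-10, and adjusted p = 0.207 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, rose from 93.1 ± 2.33 to 204 ± 3.45 FPKM. The nucleolar protein NOP56 rose from 116 ± 2.88 to 248 ± 9, and POLR1B, a subunit of RNA polymerase I, from 11 ± 0.246 to 27.8 ± 0.0885. Cytosolic ribosomal protein genes moved the other way, with 41 of 50 falling and 0 rising (43 and 0 adjusted over the list alone), among them RPL3 from 1274 ± 20.9 to 815 ± 4.9 FPKM. Their median log2 fold change was -0.27 (camera adjusted p = 4.18e-09, and adjusted p = 0.226 with an estimated correlation). After quantile normalization it was -0.10, and the call was lost (adjusted p = 0.0544).

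Genes of T-cell receptor signalling and T-lineage identity, a list in which the receptor chain genes themselves were not matched to the table, fell in 26 of 38 cases in KO1 and rose in 9, the same counts adjusted over the list alone (camera adjusted p = 0.000525, and adjusted p = 0.207 with an estimated correlation). The costimulatory receptor CD28 fell from 35.4 ± 0.483 to 7.73 ± 0.351 FPKM and the thymocyte selection gene THEMIS from 91.2 ± 9.73 to 7.05 ± 0.447. The interleukin 7 receptor gene IL7R fell from 11.7 ± 0.484 to 0.996 ± 0.139 FPKM and CD4 from 12.7 ± 1.49 to 2.81 ± 0.383. Of the 18 tested genes of immature thymocytes, 8 rose and 9 fell, the same counts adjusted over the list alone. This list did not pass (camera adjusted p = 0.491), but did among genes with FPKM of 5 or more in 3 libraries (adjusted p = 0.0468). Cholesterol synthesis and uptake genes fell in 18 of 24 cases and rose in 3, the same counts adjusted over the list alone (camera adjusted p = 0.000245, and adjusted p = 0.288 with an estimated correlation). INSIG1, a regulator of this pathway, went from 385 ± 28.5 to 157 ± 12.5 FPKM and the sterol carrier STARD4 from 71.5 ± 7.04 to 30.2 ± 2.14.

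In KO1, more genes rose than fell in 4 lists of developmental and neuronal genes. Only 17 of 39 listed HOX genes, 39 of 152 lineage transcription factors, 17 of 59 neuronal and 14 of 73 signalling genes were tested. The other listed genes did not reach 1 FPKM in 3 libraries. The counts of these lists are thus shares of the tested genes and not of the whole lists. Of 17 tested HOX genes, 9 rose and 0 fell, with HOXD13 from 1.43 ± 0.158 to 9.57 ± 1.03 FPKM (camera adjusted p = 0.0226). Of 39 lineage transcription factors, 23 rose and 9 fell, with IRX3 from 11.9 ± 0.744 to 63.2 ± 1.33 FPKM (camera adjusted p = 0.0195). Of 17 neuronal genes, 13 rose and 2 fell, with the adhesion molecule NCAM1 from 0.0913 ± 0.0799 to 17.6 ± 0.391 FPKM (camera adjusted p = 0.00472). Of 14 genes of WNT, BMP, FGF and Hedgehog signalling, 8 rose and 2 fell, with the receptor gene FGFR1 from 4.55 ± 0.129 to 12.9 ± 0.264 FPKM (camera adjusted p = 0.0488). The counts of these lists were the same adjusted over the list alone, and each list had an adjusted p = 0.207 with an estimated correlation. Among genes with FPKM of 5 or more in 3 libraries, the HOX, transcription factor and neuronal calls were lost (adjusted p = 0.161, 0.407 and 0.145). The HOX and transcription factor calls were lost after quantile normalization (adjusted p = 0.0754 and 0.0766), and the HOX call was lost without WT replicate 1 (adjusted p = 0.0502). The signalling call stood close to the threshold and was lost under 10 of 21 alternatives (adjusted p from 0.0141 to 0.172 over all of them), including those without WT replicate 1 (0.0550), WT replicate 2 (0.0521), KO1 replicate 2 (0.0595), KO2 replicate 2 (0.0501) or KO2 replicate 3 (0.0531).

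Genes of stress responses and of cell division also shifted in KO1. Of 26 genes of the integrated stress and unfolded protein responses, 17 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00386, and adjusted p = 0.332 with an estimated correlation). The chaperone CALR went from 348 ± 6.18 to 1051 ± 24.2 FPKM, and DDIT4, a stress-induced inhibitor of mTORC1, fell from 124 ± 5.43 to 20.2 ± 0.992. Of 40 genes of G2 and mitosis, 26 fell and 2 rose, the same counts adjusted over the list alone (camera adjusted p = 4.2e-05, and adjusted p = 0.332 with an estimated correlation). The mitotic kinase AURKA went from 72.3 ± 4.75 to 42.9 ± 1.21 FPKM. Of 28 chromatin modifier genes, mostly histone and DNA methylation enzymes, 15 fell and 6 rose (16 and 7 adjusted over the list alone). This list had a camera adjusted p = 0.0488, and adjusted p = 0.476 with an estimated correlation. The demethylase genes TET1 and KDM6B went from 11.7 ± 0.152 to 5.16 ± 0.198 and from 17.7 ± 1.01 to 7.46 ± 0.48 FPKM. This call too stood close to the threshold and was lost under 10 of 21 alternatives (adjusted p from 0.0136 to 0.103 over all of them). These include lists matched by exact symbol (0.103) and the fits without WT replicate 3 (0.0777), KO1 replicate 2 (0.0595), KO2 replicate 1 (0.0539), KO2 replicate 2 (0.0501) or KO2 replicate 3 (0.0531).

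The lists of replication and checkpoint genes, which the series title points to, held rises and falls in KO1, and none of the 4 passed (camera adjusted p = 0.421 to 0.929). CHEK1, which encodes CHK1, stood at 53.1 ± 2.66 FPKM in WT and 56.9 ± 2.91 in KO1 (log2 fold change 0.10 ± 0.05, adjusted p = 0.101). It passed without WT replicate 1 (0.13, adjusted p = 0.0355) or without KO1 replicate 1 (0.13, adjusted p = 0.0499). ATR, the kinase upstream of CHK1, stood at 13.1 ± 0.616 and 14.2 ± 0.528 FPKM (adjusted p = 0.0863). Of 24 genes of the ATR and CHK1 checkpoint, 7 rose and 6 fell, with the fork protein TIPIN higher and the phosphatase CDC25C lower. The median of this list was 0.04, its mean was -0.02 and its set test pointed down. Of 30 genes of origin licensing and firing, 8 rose and 8 fell, with GINS3 higher and CDT1 lower. Of 38 genes of homologous recombination and Fanconi anaemia repair, 13 rose and 13 fell, with NBN higher and RMI2 lower. The counts of these 3 lists were the same adjusted over the list alone. Of 33 replication fork genes, 8 rose and 14 fell (9 and 15 adjusted over the list alone).

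In the comparison of the libraries labelled KO2 with WT, glycolysis and hypoxia genes were again lower, and MYCN, MYC and MYC-activated genes higher. MYCN rose from 1.5 ± 0.328 to 15.8 ± 1.17 FPKM and MYC from 71.1 ± 3.65 to 144 ± 5.33. Of the 12 genes of the MYC family and its network, 5 rose and 3 fell, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.745). All 30 glycolysis and hypoxia genes fell (also 30 adjusted over the list alone), with a median log2 fold change of -1.30 (camera adjusted p = 1.73e-19, and adjusted p = 0.172 with an estimated correlation). PGK1 reached 369 ± 12.7 FPKM, ENO2 47.3 ± 1.75 and NDRG1 7.93 ± 0.802. Of 50 MYC-activated genes, 44 rose and 2 fell, the same counts adjusted over the list alone, with ODC1 at 181 ± 6.36 FPKM and NOP56 at 235 ± 11.1 (camera adjusted p = 3.93e-10, and adjusted p = 0.116 with an estimated correlation).

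Over all tested genes, 7596 changed in KO2, of which 4476 rose and 3120 fell, and 457 and 253 of these changed by 2-fold or more. The excess of rises depended on scaling: 58.9% of the changed genes were higher, against 52.9% after libraries were centred on their median and 50.8% after quantile normalization. Genes of T-cell receptor signalling and T-lineage identity, again without the receptor chains, fell in 23 of 38 cases and rose in 10, the same counts adjusted over the list alone (camera adjusted p = 0.000148, and adjusted p = 0.116 with an estimated correlation). CD4 stood at 1.1 ± 0.135 FPKM, THEMIS at 17.5 ± 1.78 and IL7R at 2.7 ± 0.153. Markers of cytotoxic and natural killer lymphocytes, of which 6 of 18 listed genes were tested, moved the other way. All 6 tested genes rose, also when adjusted over the list alone (camera adjusted p = 0.00282, and adjusted p = 0.116 with an estimated correlation). GZMA, a granule protease, went from 8.04 ± 0.68 to 41.5 ± 2.91 FPKM and the pore-forming PRF1 from 0.87 ± 0.0328 to 3.2 ± 0.413. In KO1, 3 of these 6 genes rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.189).

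Of the 18 immature thymocyte genes, 10 fell and 6 rose in KO2, the same counts adjusted over the list alone (camera adjusted p = 0.0459, and adjusted p = 0.199 with an estimated correlation). This call was lost under 6 of 21 alternatives (adjusted p from 0.00867 to 0.150 over all of them), including those without WT replicate 1 (0.0531) or WT replicate 2 (0.0505). Its median was -0.61, but 0.02 with no filter on low values.

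Cholesterol genes fell in 18 of 24 cases and rose in 3 in KO2 (19 and 3 adjusted over the list alone; camera adjusted p = 9.7e-06, and adjusted p = 0.199 with an estimated correlation). Of 40 genes of G2 and mitosis, 27 fell and 3 rose (27 and 4 adjusted over the list alone; camera adjusted p = 9.34e-06, and adjusted p = 0.242 with an estimated correlation). Of 26 stress response genes, 16 rose and 3 fell, the same counts adjusted over the list alone, with CALR at 995 ± 16.4 FPKM (camera adjusted p = 0.0215, and adjusted p = 0.314 with an estimated correlation). Of the 28 chromatin modifier genes, 14 fell and 5 rose, the same counts adjusted over the list alone. The list had a camera adjusted p = 0.0274, and adjusted p = 0.314 with an estimated correlation. Ribosomal protein genes fell in 35 of 50 cases and rose in 0, the same counts adjusted over the list alone, with a median of -0.16 (camera adjusted p = 3.21e-06, and adjusted p = 0.242 with an estimated correlation). After quantile normalization the median was -0.01 and the call was lost (adjusted p = 0.422).

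Of the 4 lists of developmental and neuronal genes, the HOX list passed in KO2. Of 17 HOX genes, 9 rose and 0 fell, with HOXD13 at 6.24 ± 0.461 FPKM (camera adjusted p = 0.0459, and adjusted p = 0.204 with an estimated correlation). This call was also lost with no filter on low values (adjusted p = 0.0814), among genes with FPKM of 5 or more in 3 libraries (0.236), after quantile normalization (0.108) and without WT replicate 1 (0.0750). Of 39 lineage transcription factors 22 rose and 9 fell, of 14 signalling genes 11 rose and 2 fell, and of 17 neuronal genes 9 rose and 1 fell. The counts of these 4 lists were the same adjusted over the list alone. The last 3 did not pass (camera adjusted p = 0.101, 0.0538 and 0.0813). The signalling list passed under 4 of 21 alternatives, including that without KO2 replicate 3 (adjusted p = 0.04999), and the neuronal list passed without WT replicate 3 (adjusted p = 0.0485).

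NOTCH pathway genes rose in 18 of 23 cases and fell in 4 in KO2, the same counts adjusted over the list alone (camera adjusted p = 0.0418, and adjusted p = 0.314 with an estimated correlation). The ligand gene JAG1 rose from 2.18 ± 0.205 to 13.8 ± 0.118 FPKM and the receptor gene NOTCH1 from 8.85 ± 0.455 to 14.7 ± 0.703, while NOTCH3 fell. The call was lost among genes with FPKM of 5 or more in 3 libraries (adjusted p = 0.1004) and without WT replicate 1 (0.0564). In KO1, 13 of the 23 rose and 6 fell, the same counts adjusted over the list alone, with a median of 0.40 against 0.36 in KO2. The list did not pass in KO1 (camera adjusted p = 0.145), but did with no filter on low values (0.0138), and the lines were not shown to differ in it (camera adjusted p = 0.445 for KO2 against KO1). Interferon-stimulated genes fell in 16 of 31 cases and rose in 3, the same counts adjusted over the list alone (camera adjusted p = 0.00647, and adjusted p = 0.116 with an estimated correlation). Among genes with FPKM of 5 or more in 3 libraries this call was lost (adjusted p = 0.125). In KO1, 16 of the 31 fell as well and 8 rose, the same counts adjusted over the list alone. The interferon list did not pass there (camera adjusted p = 0.333). Its median was -0.23 in KO1 and -0.15 in KO2, and its mean -0.12 and -0.27. Of 40 listed germ-cell and cancer-testis genes, only 6 were tested. Of these, 5 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.15 with an estimated correlation). That call was lost with no filter on low values (adjusted p = 0.122). In KO1, 3 of these 6 genes rose and 2 fell, and the list did not pass (camera adjusted p = 0.526).

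The 4 replication and checkpoint lists did not pass in KO2. CHEK1 stood at 50.9 ± 1.16 FPKM (log2 fold change -0.06 ± 0.05, adjusted p = 0.331) and ATR at 14 ± 0.346 (adjusted p = 0.173). Of 24 checkpoint genes, 7 rose and 7 fell (camera adjusted p = 0.429), with a median of 0.01, a mean of -0.05 and a set test that pointed down. Of 30 origin genes, 8 rose and 11 fell (camera adjusted p = 0.157). Of 33 replication fork genes, 7 rose and 16 fell, including the thymidine kinase gene TK1 from 18 ± 1.32 to 7.05 ± 1.05 FPKM. The counts of these 3 lists were the same adjusted over the list alone. The fork list stood at the threshold (camera adjusted p = 0.0507) and passed under 10 of 21 alternatives (adjusted p from 0.0351 to 0.127 over all of them), including those without WT replicate 3 (0.0485), KO1 replicate 3 (0.0454) or KO2 replicate 2 (0.0398). Of 38 repair genes, 11 rose and 18 fell (12 and 18 adjusted over the list alone; camera adjusted p = 0.101).

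**Figure D2:**
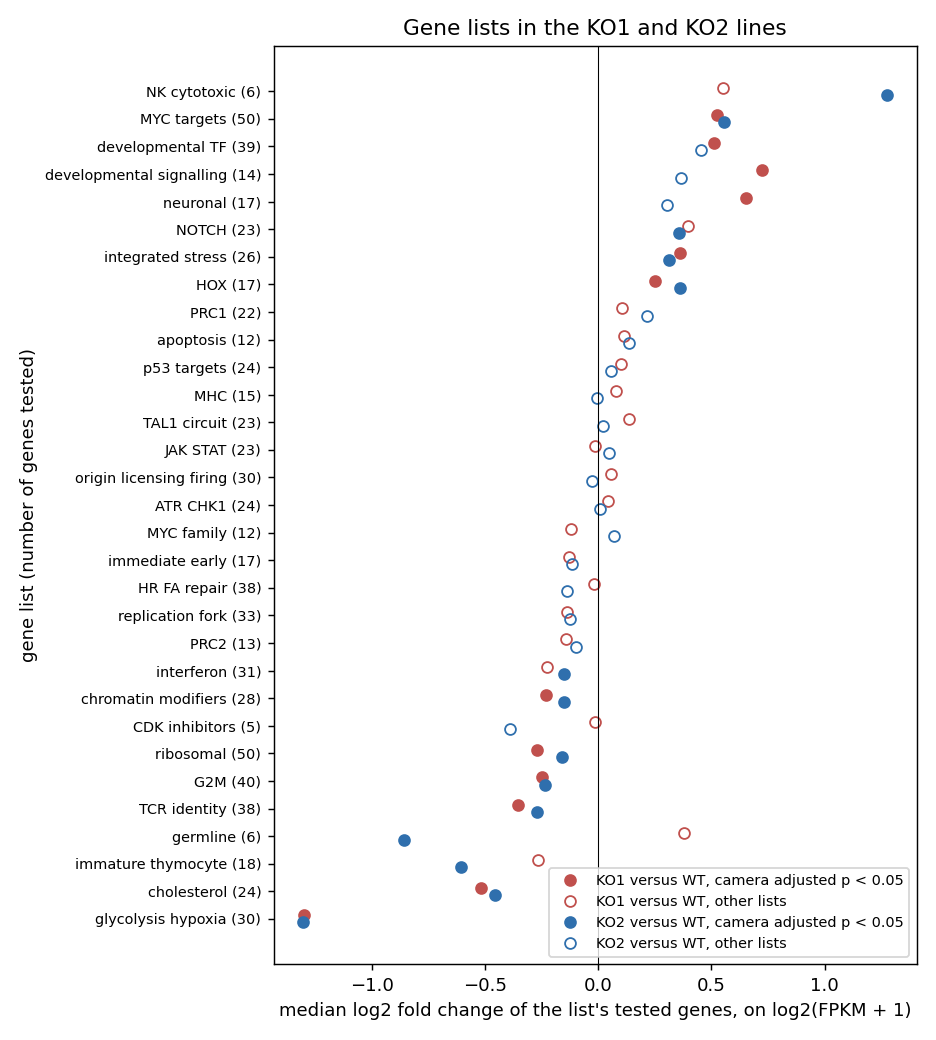
Median log2 fold change against WT, on log2(FPKM + 1) (horizontal axis), of the tested genes of each of the 31 lists with 5 or more tested genes (vertical axis, number tested in parentheses), for KO1 (red) and KO2 (blue); filled points have a camera adjusted p under 0.05. Both lines had a median of -1.30 for glycolysis and hypoxia and medians of 0.52 and 0.56 for MYC-activated genes.

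The largest rises shared by both edited lines were those of NRIP1, ROBO1, APP and CDH2, and the largest shared falls those of DNTT and CD1E. NRIP1, a nuclear receptor corepressor, rose from 0.0801 ± 0.0851 to 25.1 ± 2.13 FPKM in KO1 and 19 ± 0.779 in KO2. The guidance receptor gene ROBO1 rose from 0.0619 ± 0.107 to 31.7 ± 0.653 and 17.9 ± 0.476, and the amyloid precursor gene APP from 0.344 ± 0.11 to 74.9 ± 2.81 and 19.3 ± 0.33. N-cadherin (CDH2) rose from 1.04 ± 0.214 to 54.3 ± 3.62 and 24.1 ± 0.474, and cyclin D2 (CCND2) from 0.449 ± 0.125 to 28 ± 1.34 and 14.9 ± 0.212. TNIK, SLC7A8, CTBP2, PLEK, IGF2BP2, SLC27A2 and EPHA3 completed the 12 largest shared rises, with the smaller of their log2 fold changes between 3.02 and 3.47. DNTT, which encodes the terminal deoxynucleotidyl transferase of immature lymphocytes, fell from 135 ± 6.7 to 3.61 ± 0.54 and 4.86 ± 0.421 FPKM. The lipid antigen-presenting gene CD1E fell from 174 ± 12.1 to 6.59 ± 0.965 and 8.55 ± 0.585, and CD1C and CD1A fell as well. So did ADM, PFKFB4 and ALDOC, which are on the glycolysis and hypoxia list, and BHLHE40, MAL, TSHR, C10orf107 and GCSAM.

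The antiapoptotic gene BCL2 rose from 6.83 ± 0.515 to 16.1 ± 0.173 FPKM in KO1 and 15.7 ± 0.325 in KO2. TAL1, a T-lineage leukaemia oncogene, fell from 52.9 ± 1.18 to 30 ± 0.465 and 47.5 ± 1.78. Of 12 BCL2 family genes, 4 rose and 1 fell in KO1, and 4 rose and 2 fell in KO2 (camera adjusted p = 0.346 and 0.655). Of 23 TAL1 circuit genes, 11 rose and 8 fell in KO1, and 8 rose and 9 fell in KO2 (camera adjusted p = 0.442 and 0.745). The lists of cytokine receptor, JAK and STAT genes (camera adjusted p = 0.724 and 0.655) and of cyclin-dependent kinase inhibitors (0.421 and 0.139) did not pass either. CDKN2A was listed at 0 in all 9 libraries, HOXA9 and IL6R were listed at 0 in WT and below 1 FPKM in the other libraries, and CDKN1A averaged under 1 FPKM in each group. None of these 4 genes was tested.

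In all, 6145 genes changed the same way in both lines, 3525 higher and 2620 lower, and 573 of them by 2-fold or more in both (373 higher and 200 lower). Independent lists of these sizes would share 1593 higher and 996 lower genes, and 25.4 and 7.2 at 2-fold. Both comparisons share the WT libraries. Simulated unchanged groups against shared controls gave 0 genes changed the same way in each of 100 simulations. With no change put in, hardly any call could arise, so this count does not measure how much of the real overlap the shared controls explain. The simulations hold only noise between libraries. A shift of the WT cultures as a whole would move genes the same way in both comparisons, and it was not tested. The log2 fold changes correlated across genes, which are not independent replicates, with r = 0.867, against a mean of 0.507 in the simulations (0.279 to 0.678). Their covariance was 0.293 against a simulated 0.00689 (0.00393 to 0.0118). The 3 WT libraries cannot be divided into parts of 2, so part of the excess over independent lists may come from the shared controls. Against the mean of the edited lines, 8135 genes differed from WT, 4527 higher and 3608 lower (55.6% higher, and 49.96% after quantile normalization).

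**Figure D3:**
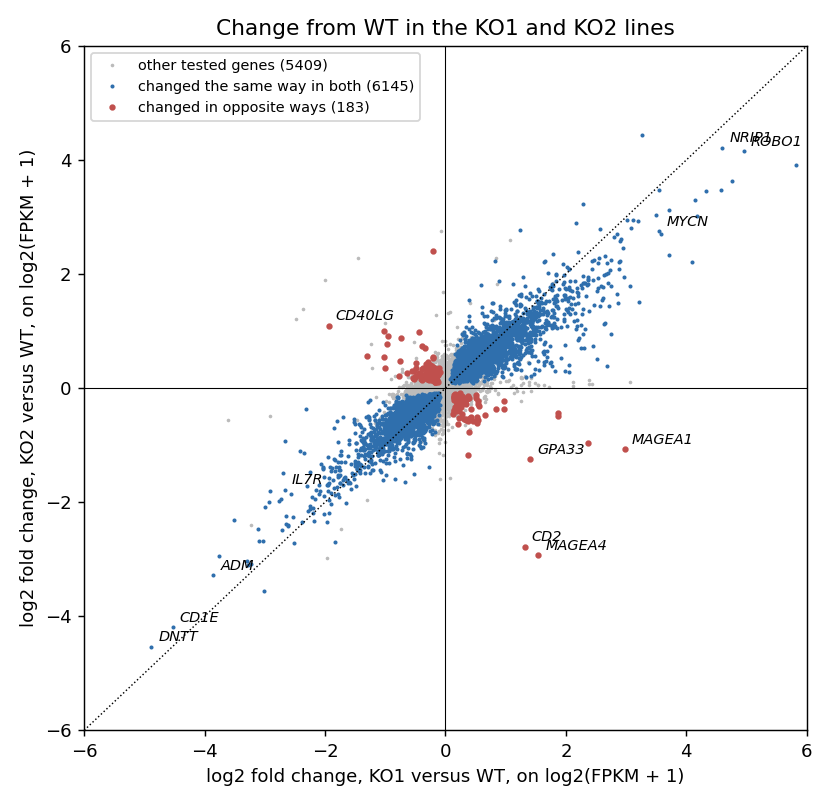
Log2 fold change against WT, on log2(FPKM + 1), in KO1 (horizontal axis) and KO2 (vertical axis) for the 11737 tested genes. Blue points are the 6145 genes changed the same way in both lines, red points the 183 changed in opposite ways, grey points the rest, and the dotted line marks equal changes.

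The edited lines also differed from each other, with MAGEA4 and CD2 lower and CD40LG higher in KO2. MAGEA4, a cancer-testis antigen, stood at 21.9 ± 1.49 FPKM in KO1 and 0.0348 ± 0.0302 in KO2 (log2 fold change -4.46 ± 0.07, adjusted p = 6.11e-11), against 6.86 ± 0.0939 in WT. The adhesion receptor CD2 stood at 90.6 ± 3.59 and 4.38 ± 0.789 (-4.10 ± 0.09, adjusted p = 8.77e-10), against 35.8 ± 0.774 in WT. MAGEA1, PAPPA and GPA33 were also lower in KO2, and CHRDL1, listed at 0 in the WT libraries, stood at 7.36 ± 0.306 in KO1 and 0.0739 ± 0.0158 in KO2. The CD40 ligand gene CD40LG went the other way, at 1.16 ± 0.224 FPKM in KO1 and 16.7 ± 0.573 in KO2 (3.04 ± 0.09, adjusted p = 6.89e-09). It was followed by ALDH1B1, SHISA2, LGALS3BP, TCEAL4 and RHOU.

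Over all tested genes, 3596 differed between KO2 and KO1, 2146 higher and 1450 lower in KO2 (59.7% higher), and 42 and 104 of these by 2-fold or more. The balance of directions depended on scaling: 47.9% were higher after libraries were centred on their median and 49% after quantile normalization. Of the 6145 genes changed the same way in both lines, 1767 differed between them, with the larger change in KO1 for 1252 and in KO2 for 515. Of 39 lineage transcription factors, 17 were lower and 5 higher in KO2 than in KO1, the same counts adjusted over the list alone (camera adjusted p = 0.00165). Of 17 neuronal genes, 9 were lower and 4 higher, the same counts adjusted over the list alone (camera adjusted p = 0.00279). Of 14 signalling genes, 7 were lower and 2 higher (7 and 4 adjusted over the list alone; camera adjusted p = 0.0232). Each of these lists had an adjusted p = 0.131 with an estimated correlation. The neuronal call was lost among genes with FPKM of 5 or more in 3 libraries (adjusted p = 0.0547) and the signalling call after quantile normalization (0.0583).

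Cytotoxic lymphocyte markers were higher in KO2 than in KO1 in 4 of 6 cases and lower in 0 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0107). They include EOMES, a transcription factor of these cells, at 0.924 ± 0.131 FPKM in KO1 and 5.41 ± 0.524 in KO2. Of 6 germ-cell genes, 4 were lower and 1 higher, the same counts adjusted over the list alone (camera adjusted p = 0.00392). Both lists had an adjusted p = 0.131 with an estimated correlation, and both calls were lost with no filter on low values (adjusted p = 0.0863 and 0.0631). Genes of the TAL1 circuit were lower in 9 of 23 cases and higher in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0134, and adjusted p = 0.131 with an estimated correlation). This call was lost with no filter (0.0631) and among genes with FPKM of 5 or more in 3 libraries (0.375). Interferon-stimulated genes were lower in 10 of 31 cases and higher in 5, the same counts adjusted over the list alone (camera adjusted p = 0.0431, and adjusted p = 0.131 with an estimated correlation). This call was lost under 4 of 21 alternatives (adjusted p from 0.0312 to 0.0938 over all of them). These include median centring (0.0612) and the fit without KO1 replicate 1 (0.0583). Near the threshold without passing stood the glycolysis and hypoxia list, with 7 of 30 genes higher in KO2 and 2 lower (camera adjusted p = 0.0552). So did the immature thymocyte list, with 5 of 18 higher and 8 lower (camera adjusted p = 0.0515). Each passed under 5 of 21 alternatives, and neither with an estimated correlation (adjusted p = 0.785 and 0.176).

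Ribosomal protein genes were higher in KO2 than in KO1 in 18 of 50 cases and lower in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 0.00165, and adjusted p = 0.511 with an estimated correlation). Origin genes were lower in 11 of 30 cases and higher in 5 (12 and 5 adjusted over the list alone; camera adjusted p = 0.036, and adjusted p = 0.337 with an estimated correlation). That call was lost with no filter (0.0631) and without KO2 replicate 1 (0.0622). Replication fork genes were lower in 10 of 33 cases and higher in 3 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0431, and adjusted p = 0.344 with an estimated correlation). That call was lost with no filter (0.0631) and without KO1 replicate 1 (0.0641), KO1 replicate 3 (0.0604), KO2 replicate 1 (0.0622) or KO2 replicate 3 (0.0853). Repair genes were lower in 9 of 38 cases and higher in 1, the same counts adjusted over the list alone, and the list stood at the threshold without passing (camera adjusted p = 0.0515, and adjusted p = 0.637 with an estimated correlation). It passed under 13 of 21 alternatives (adjusted p from 0.0291 to 0.191 over all of them), including those without WT replicate 1 (0.0449), WT replicate 2 (0.0497), WT replicate 3 (0.0499), KO1 replicate 1 (0.0318), KO1 replicate 2 (0.0318) or KO2 replicate 3 (0.0291).

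CHEK1 was lower in KO2 than in KO1 (log2 fold change -0.16 ± 0.05, adjusted p = 0.0361). It no longer passed without KO1 replicate 2 (0.0788), KO1 replicate 3 (-0.12, adjusted p = 0.119), KO2 replicate 1 (0.0991), KO2 replicate 2 (0.111) or KO2 replicate 3 (0.0546), nor with no filter (0.0511), without the mean-variance trend (0.0628) or with a replicate block (0.0549).

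Genes that differed between the edited lines were partly grouped along chromosomes. Among 8135 genes with a mean of 5 FPKM or more, the running median of 31 neighbouring genes left the range of shuffled gene orders over long runs. On chromosome 2, 203 of 250 genes from BCL2L11 to DTYMK passed the test and were lower in KO2, and the median of the run was -0.35. In a shorter run on this chromosome, 20 of 30 genes from COX5B to NCK2 passed and were higher in KO2 (median 0.28). On chromosome 9, 146 of 159 genes from TMEM38B to EHMT1 were higher in KO2, with a median of 0.47. On the X chromosome, 139 of 192 genes from PLCXD1 to ELF4 were higher in KO2 (median 0.28), and so were 31 of 39 from MTMR1 to IL9R (median 0.33). On chromosome 7, 24 of 48 genes from CPSF4 to SRPK2 were higher (median 0.23). Against WT, the longer chromosome 2 run had a median of -0.28 in KO2 and 0.10 in KO1, and the chromosome 9 run had -0.33 in KO1 and 0.16 in KO2. The longer X run lay below WT in both lines, at -0.47 in KO1 and -0.20 in KO2, and the shorter one had -0.26 and 0.00467. The chromosome 7 run had -0.05 in KO1 and 0.12 in KO2. Searched in the same way against WT, with wider limits from shuffled orders (0.401 and 0.345), 180 genes lay in runs in KO1, on chromosomes 9 and X, and 116 in KO2, on chromosomes 2 and X. How many members of the gene lists lie in the runs between the edited lines was not examined.

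**Figure D4:**
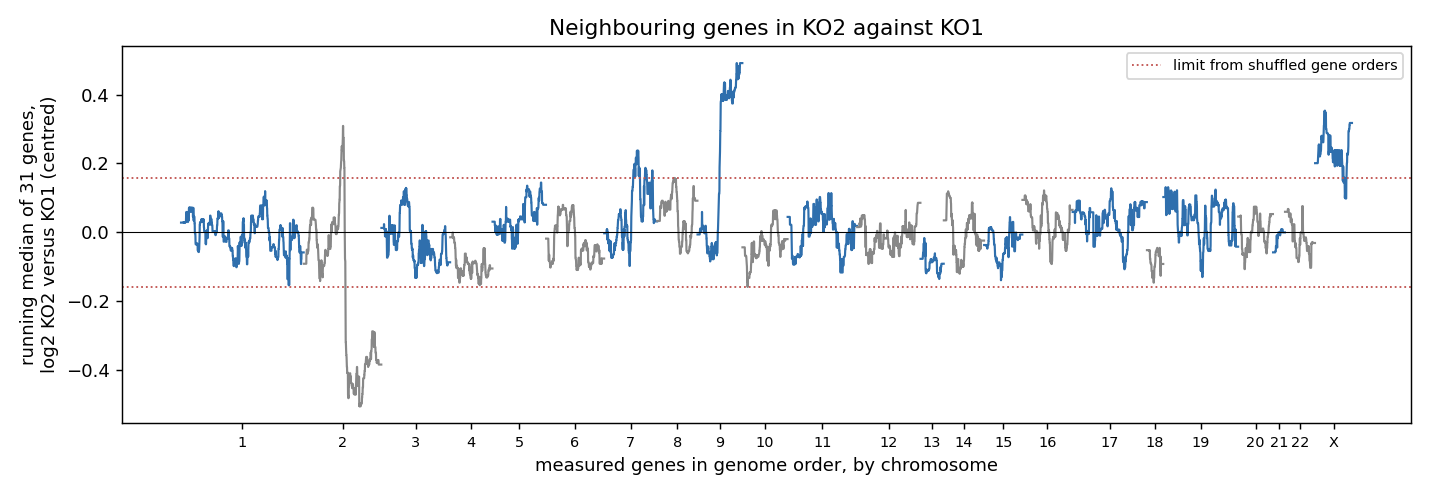
Running median over 31 neighbouring genes of the log2 fold change of KO2 against KO1, centred on all placed genes (vertical axis), for 8135 genes in genome order by chromosome (horizontal axis, alternating colours); dotted lines mark the limit of 0.158 from shuffled gene orders. The longest runs lie on chromosomes 2, 9 and X.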

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

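The tests of left-out genes within runs of neighbours were chosen only after the result was seen. The edited lines differed from each other by a direct test, KO2 against KO1, for 3596 genes and 10 gene lists. Genes that changed by 2-fold or more in opposite directions from WT were singled out as well. CD2 rose in KO1 and fell in KO2 (log2 difference of KO2 against KO1 -4.10), as did GPA33 (-2.66), MAGEA1 (-4.05) and MAGEA4 (-4.46), and CD40LG fell in KO1 and rose in KO2 (3.04).

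Splits of 6 libraries into 3 and 3 number 10, which is too few for a share under 0.05. In each of the 6 tests that follow, 1 split, the real one, gave a result as large. For KO1 against WT the real split gave 7923 genes and 12 lists, and the highest other gave 0 genes and 10 lists. For KO2 against WT these were 7596 genes and 14 lists, against 2 genes and 10 lists. For KO2 against KO1 they were 3596 genes and 10 lists, against 2 genes and 5 lists. Against WT, other splits with hardly any gene called thus came close to the real list counts. Those list counts separate the real groups from other splits only weakly. Splits that mix the groups unevenly may carry part of the real differences. Of the 84 splits into 3 and 6 libraries, fitted as 2 groups, 1, the real one, reached its 7003 genes. The highest other gave 1472, so a chance sorting of these libraries can be excluded there. Of 100 drawn splits into 3 groups, 1, the real one, reached 6145 genes changed the same way (highest other 5510). A chance sorting of the libraries can be excluded for that count as well. Both tests exchange cultures between lines, so they say nothing of chance differences between single lines or edits. For the correlation of 0.867 between the changes in KO1 and KO2, chance cannot be excluded by these splits, of which 24 of 100 reached it (highest other 0.964). The drawn splits mix libraries of groups that differ, so they carry part of the real differences, and simulated unchanged groups with shared controls reached at most 0.678.

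The 3596 genes that differ between the edited lines were weighed further. A single library did not decide the count, whose lowest value over the 9 left-out libraries was 2643. Runs of neighbouring genes shifted together held 23% of the genes that differ (581 of 2531 with a mean of 5 FPKM or more). They held 9.11% of all placed genes. The runs found thus do not account for most of the differences, but shorter or more weakly shifted segments could be missed. Within runs found on every other gene, 93% of the 372 left-out genes between them shifted in the direction of the run, so a difference in the dosage of chromosome segments between the lines may account for the genes in runs. Regional regulation of expression stays open for these genes. For the others, dosage of segments that were missed stays open. So does a difference between clones, between edits or between cultures, and none of these was tested.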

How the results depend on the processing

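Matching lists by exact symbol and leaving out small RNA genes were chosen only after seeing the data. Of the values that answer a comparison, 221 under alternatives kept their direction and side of the threshold or lay close to the reported value. Close meant within 1.5 times a count, or within 0.0121 of the correlation. Of the others, 12 were weaker, 2 were stronger and 3, all correlations, moved. Only the change of EZH2 could reverse by these rules, and it did not. Of the values of named genes 9722 kept their call, 108 lost it and 52 gained one; for lists these were 1844, 59 and 41.

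Requiring a 2-fold change left 986 (KO1), 710 (KO2), 146 (KO2 against KO1), 815 (mean of the lines) and 573 genes (same way in both), which follows from its construction, and an adjusted p under 0.01 left 2100 for KO2 against KO1. With an estimated correlation 0, 0 and 0 lists passed for KO1, KO2 and KO2 against KO1, and with fry, which does not compare a list with other genes, 25, 29 and 15. List counts fell to 7 after quantile normalization (KO1), to 9 among genes with FPKM of 5 or more in 3 libraries (KO2), where fewer genes were tested, and to 6 with no filter (KO2 against KO1). Exact symbols gave 10, 16 and 10 lists. The correlation was 0.844 with no filter, 0.853 after quantile normalization and 0.852 to 0.870 over the left-out libraries, lowest without KO2 replicate 3. Where no cause is given, the cause was not tested. Left-out libraries gave 7339 to 7935 genes for KO1, 6869 to 7741 for KO2 and 2643 to 4081 for KO2 against KO1.

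Numbers of replicates do not pair the libraries: 3 of 9 same-number pairs correlated above 0.1 (-0.287 to 0.318) and 3 of 9 were best with their own number. With a replicate block, 7694, 7339, 3135 and 7915 genes changed in KO1, KO2, KO2 against KO1 and the mean of the lines, 5922 the same way in both, and 10, 15 and 12 lists. The DESeq2 alternative was not run, since FPKM are not counts. In simulated data 28% to 38% of changes of 0.25 were recovered. Small changes can be missed, but far fewer genes changed in the simulated data than in the real data. These shares thus do not measure how often small changes were missed.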

Other observations

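The tests of swapped labels, of scaling, of the neighbours of EZH2 and of culture state were chosen only after the result was seen. Among subunits of Polycomb repressive complex 1, which binds H3K27me3, BMI1 stood at 39.3 ± 2.41 FPKM in WT, 90.5 ± 10.8 in KO1 and 72 ± 6.53 in KO2, and RNF2, CBX2 and CBX6 rose in both lines. Of 22 tested subunits, 9 rose and 6 fell in KO1 and 11 rose and 5 fell in KO2, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.485 and 0.236). Among genes activated by p53, TP53INP1 fell from 7.89 ± 0.383 to 1.93 ± 0.349 and 1.85 ± 0.196 FPKM, and AEN rose. Of 24 such genes, 8 rose and 7 fell in KO1 and 5 rose and 9 fell in KO2, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.907 and 0.396). Its medians were 0.10 and 0.06, while its means were -0.02 and -0.05 and its set tests pointed down. The immediate early gene EGR1 fell from 5.56 ± 0.105 to 0.255 ± 0.0162 and 0.291 ± 0.19 FPKM. Of 17 immediate early and heat shock genes, 2 rose and 7 fell in KO1 and 4 rose and 7 fell in KO2, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.335 and 0.35).

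Of 15 tested genes of MHC class I and II and antigen processing, 7 rose and 5 fell in KO1 (7 and 6 adjusted over the list alone) and 5 rose and 7 fell in KO2, the same counts adjusted over the list alone. The list did not pass (camera adjusted p = 0.907 and 0.474); its set tests pointed down, while its medians were 0.08 and -0.01 and its means 0.02 and 0.01. The class I gene HLA-B rose from 29.2 ± 0.574 to 77.3 ± 5.77 and 67.3 ± 2.19 FPKM, while HLA-E fell from 29.4 ± 1.82 to 10.7 ± 1.16 and 13.9 ± 0.416. The B-cell receptor component CD79A stood at 27.5 ± 2.57 FPKM in WT, 54.9 ± 5.52 in KO1 and 21 ± 1.65 in KO2, a rise and a fall. The matrix protein SPARC rose from 4.06 ± 0.503 to 15.4 ± 1.26 and 11.6 ± 0.506 FPKM. The myeloid gene S100A9 was listed at 0 in the WT libraries and stood at 0.36, 1.35 and 1.01 FPKM in the KO1 libraries and at 2.07, 3.37 and 2.68 in the KO2 libraries. The lists of B-cell, myeloid, erythroid, and epithelial and fibroblast markers had fewer than 5 tested genes and no set test. Of 4 B-cell genes, 3 rose and 1 fell in KO1, and 1 rose and 2 fell in KO2. Of 4 myeloid genes, 3 rose and 1 fell in each line. Of 4 epithelial and fibroblast genes, 2 rose and 0 fell in KO1, and 3 rose and 1 fell in KO2. The 1 erythroid gene tested fell in both lines.

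The EZH2 transcript was higher in both lines labelled KO. A swap of the WT and KO labels would lower developmental genes in the KO lines, if loss of the complex raises them, whereas all 4 lists (HOX, lineage transcription factors, developmental signalling and neuronal genes) had more rises than falls in both lines. Rises also outnumbered falls over all tested genes (4177 against 3746 in KO1 and 4476 against 3120 in KO2). An excess of rises alone is thus not particular to these lists. The counts of the lists were known before this test was written. They argue only weakly against a swap, and only if loss of the complex raises these genes. In KO2, 3 of the 4 lists did not pass the set test. Scaling of the libraries does not account for it, since the lowest log2 difference over both lines and both scalings was 0.17. Extra copies of a region wide enough to hold most of the 30 nearest neighbours of EZH2 are argued against. The median log2 difference of these neighbours between KO1 and WT, centred on all placed genes, was -0.073, and 0.022 between KO2 and WT. A gain of EZH2 with few neighbours would leave this median in place, so such a gain stays open. A response to the edit, or to the higher MYC and MYCN transcripts, stays open as well, untested.

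Glycolysis and hypoxia genes were lower in both lines labelled KO. Scaling of the libraries does not account for this, since the higher of the medians in the lines was -1.31 after each library was centred on its median. The culture state of the WT line at harvest, such as density or oxygen supply, cannot be told apart from an effect of the edit, because each line was grown separately and the groups are the lines. The 10 hypoxia-induced members outside glycolysis had a median of -1.95 in KO1 and -1.68 in KO2, but these genes were part of the fall already seen, so the values cannot support the explanation. Both explanations stay open.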
